A study of Mus musculus with 6 samples.

How the data were processed

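Total RNA was sequenced from F121-9 cells, a female mouse embryonic stem cell line from a cross of the CAST and 129 strains, grown in serum-free medium with LIF and the 2i inhibitors. The cells were transfected with 30 nM of a nontargeting siRNA (siNT, 3 libraries) or of an siRNA against ZC3H4 (siZC3H4, 3 libraries). Per the labels, the libraries were stranded and depleted of ribosomal RNA, and ERCC spike-in RNA was added. The submitters' processing notes name cutadapt 1.14, STAR 2.7.31, featureCounts, DESeq2 and the mouse genome build mm10. They give no order of the steps, no strandedness of the counting, no size of the upstream window and no annotation release, so the uaRNA regions are used as deposited.

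The authors deposited 2 tables, one of upstream antisense RNAs (uaRNAs, transcribed away from the promoter on the strand opposite to the gene) and one of the exons of each gene, with 1 column per library. The deposited values are a signal, described per the file headers as normalised counts. Checked on the values, each column holds whole reads divided by 1 factor per library: 1.356, 1.319 and 1.298 for siNT replicates 1, 2 and 3, and 1.0, 1.717 and 1.296 for siZC3H4 replicates 1, 2 and 3. The factors were the same in both tables, and after multiplication 100% of values lay within 0.05 of a whole read count. The column numbers of the tables differ from the sample numbers in the library descriptions, so columns were assigned by group and replicate as written in both. The exon-based table lists 13088 genes, and 5867 uaRNAs are listed in the uaRNA table, each with its gene in the exon-based table. Neither table lists ERCC sequences. The symbols of 17 genes are written as dates, and these genes were not named.

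The libraries labelled siZC3H4 were compared with those labelled siNT in each table with limma 3.58.1 in R 4.3.3, on log2(value + 1) at the deposited scale, two-sided, without a covariate. Fold changes are on this log2(value + 1) scale and understate the change of weakly expressed genes. uaRNAs with a mean of at least 5 over the 6 libraries and genes with a mean of at least 10 were tested, and an adjusted p (Benjamini-Hochberg over a table) under 0.05 was called. Each uaRNA was also compared with its own gene by a limma fit of the difference of their log2 values per library. A single value per library was compared by an exact permutation test, two-sided, whose smallest p with 3 against 3 libraries is 0.1. The tests of each table and of gene lists in the exon-based table, the minima, the lists and the rule for named genes were fixed before the data were examined. Tests of neighbouring genes were not in that design, and the limits for their odds ratios were written before those tests were run. Tests of uaRNAs by gene list or by the level of the gene were chosen after the result was seen.

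The rule names Zc3h4, and in each table the 10 largest rises and 10 largest falls among those past the threshold with a mean of at least 20 in the higher group and no overlap between the groups. It also names the 3 smallest p of each table, up to 4 members of each list by p, and the own gene of each uaRNA named for its change. Gene symbols that are only an identifier were passed over among the largest changes (2 rises and 1 fall). The 27 gene lists cover naive pluripotency, formative and primed pluripotency, the 2-cell-like state, primitive endoderm, mesoderm and primitive streak, neural, trophoblast, germline and fibroblast (feeder) markers. They also cover Restrictor and partner proteins, Integrator, the nuclear exosome, cleavage and polyadenylation, elongation control, replication-dependent histones, small nucleolar RNA host genes and long noncoding RNAs. The remaining lists hold p53 targets, interferon response, integrated stress, immediate early genes, MEK-ERK feedback targets, Wnt targets, cholesterol synthesis, glycolysis, ribosomal proteins and mitochondrially encoded genes. The 23 lists with at least 5 tested members were tested against the other genes with camera of limma at a preset correlation of 0.01 and again with an estimated correlation. They were also tested with fry, which asks whether a list's genes move on balance 1 way and makes no comparison with other genes.

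Read counts recovered from the deposited values were also tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. Neighbouring genes were taken from GENCODE M21, in which 13083 of the 13088 gene identifiers were found, all on the same chromosome and strand. Odds ratios were stratified by expression level, and for neighbours by gene type as well (Mantel-Haenszel). Their intervals take genes or uaRNAs as independent with the 6 libraries held fixed, so they do not measure the spread between libraries. Other settings covered pseudocounts of 0.5 and 5, no minimum value, a mean of at least 50, rescaling by the median ratio or upper quartile of the exon-based table or by the median ratio of the uaRNAs, limma with trend, a fold of at least 1.5, a replicate block, and leaving out each library. Rescaling by ERCC sequences was not run. In data simulated from these counts with 200 changed entries, limma called 17.6% of uaRNAs and 77% of genes changed 2-fold, and 87.6% and 99% of those changed 4-fold. Of its calls, 6.93% among uaRNAs and 4.89% among genes were unchanged entries. With edgeR these shares were 6.52% and 7.18%, and with DESeq2 they were 2.2% and 15.3%. The simulated entries changed in both directions and were few, unlike the broad rise of uaRNAs in the data, so these shares need not hold for the data. The sequence content of the uaRNA regions and allele-specific expression were not analysed here.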

Results

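Total RNA of mouse embryonic stem cells was measured in 3 libraries labelled siNT (nontargeting siRNA) and 3 labelled siZC3H4 (siRNA against ZC3H4, the zinc finger protein of the Restrictor complex, which attenuates transcription together with WDR82). The recovered reads in the exon-based table came to 25697777, 29244604 and 29795394 for siNT replicates 1, 2 and 3, and to 22167340, 38123686 and 28824678 for siZC3H4 replicates 1, 2 and 3. The uaRNA table held 1239818, 944172 and 970085 reads for siNT and 841237, 1422365 and 1105983 for siZC3H4. The entries upstream of Parp2 and Ccdc107, which lie beside the abundant noncoding RNA genes Rpph1 and Rmrp, took 60.62% to 68.94% of the uaRNA values of a library. siNT replicate 1 stood apart: its median gene value was 573.7, against 701.4 to 716.4 in the other 5 libraries.

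The siRNA targets Zc3h4 (ENSMUSG00000059273, mm10 chromosome 7, 16400500 to 16437696, plus strand), so its own mRNA gives the size of the knockdown at the RNA level. Zc3h4 mRNA was not lower in the libraries labelled siZC3H4. Its normalised read count was 2428 ± 629 (SD, n = 3) in siNT and 2355 ± 241 (SD, n = 3) in siZC3H4, and the values of the groups overlapped. The log2 fold change was -0.01 ± 0.21 (SE), with a 95% confidence interval from -0.50 to 0.47 and an adjusted p of 0.987 (exact permutation p = 1). The lower bound corresponds to 70.8% of the siNT level. Without siNT replicate 1 the log2 fold change was -0.24 and without siNT replicate 3 it was 0.15. Because the target's level goes against the label, the groups are named by their labels throughout, and every direction given here is that of the libraries labelled siZC3H4 relative to those labelled siNT. Of the 17 tested genes for Restrictor and its partner proteins, 0 passed the threshold in limma, also when adjusted over the list alone, and 0 in edgeR (camera adjusted p = 0.952). The smallest p, and the only one under 0.05 unadjusted, belonged to Zc3h8, which encodes another CCCH zinc finger protein, at 202 ± 28.5 in siNT and 305 ± 7.58 in siZC3H4 (SD, n = 3; log2 fold change 0.60, adjusted p = 0.0518). Zc3h8 passed under both rescalings to the exon-based table, with DESeq2 and without siNT replicate 1. Srrt, which encodes the RNA-processing protein ARS2, was at 7234 ± 1187 in siNT and 9276 ± 1276 in siZC3H4 (SD, n = 3; adjusted p = 0.327).

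**Figure D1:**
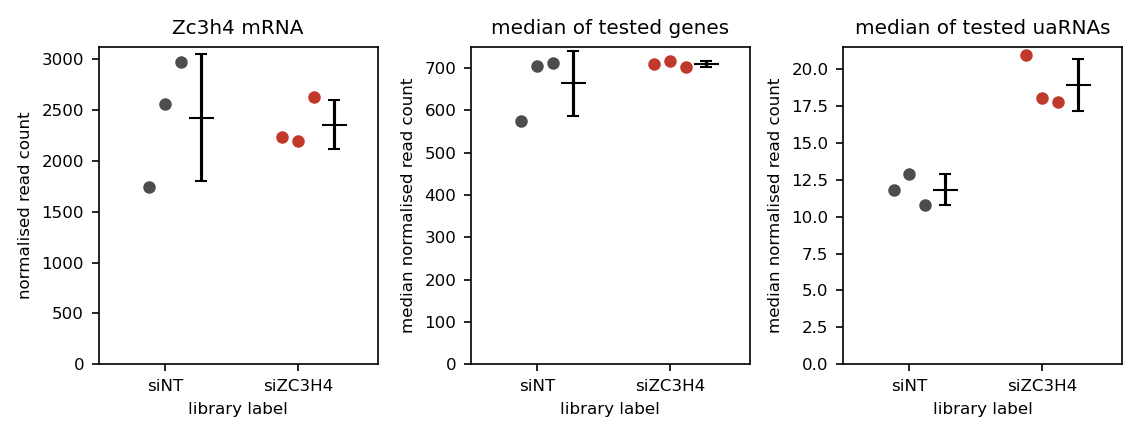
Points show the normalised read count of Zc3h4, the median over all tested genes and the median over all tested uaRNAs in each of the 6 libraries, with the mean ± SD of each group (n = 3) beside them; every axis starts at 0. Zc3h4 values overlap between the labels, the gene median of siNT replicate 1 is the lowest at 573.7, and the 3 uaRNA medians of siZC3H4 (17.75 to 21) lie above the 3 of siNT (10.79 to 12.89).

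The uaRNA table addresses whether transcription upstream of promoters is released when Restrictor is targeted. uaRNAs were broadly higher in the libraries labelled siZC3H4. The uaRNA upstream of Magt1, which encodes a subunit of an oligosaccharyltransferase (ENSMUSG00000031232, chromosome X, 105968084 to 106011802, minus strand), rose from 20.6 ± 0.166 to 244 ± 26.3 (SD, n = 3). That is a log2 fold change of 3.49 ± 0.23 (SE) at an adjusted p of 0.000618, the smallest p in the table. The uaRNA of the growth factor gene Bmp4 (chromosome 14, 46383525 to 46390582, minus strand) rose from 4.51 ± 1.41 to 46.4 ± 9.45 (SD, n = 3). Those of Cnot8, which encodes a deadenylase subunit of the CCR4-NOT complex, and of Ampd2, an AMP deaminase gene, rose from 15.5 to 117 and from 6.30 to 51.6. In all, 906 of 3282 tested uaRNAs rose (27.61%) and 18 fell, with a median rise of 2.465-fold, and 756 rises were of at least 2-fold.

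The other uaRNAs with the largest rises lay upstream of Phpt1 (log2 fold change 3.00), Avpi1 (2.75), the kinase gene Cdkl3 (2.72), Taf7, which encodes a subunit of the general transcription factor TFIID (2.68), Cnot4 (2.67) and Vps4b, which encodes an ATPase of membrane scission (2.65). Of the 10 named rises, Cnot4 (from 11.7 ± 10.0 to 52.6 ± 16.1, SD, n = 3; adjusted p = 0.0417) lost its call without siZC3H4 replicate 1, 2 or 3, at adjusted p of 0.129, 0.0783 and 0.0853, with DESeq2 (0.113), with a pseudocount of 0.5 (0.0579) and without a minimum value (0.0762). Without siNT replicate 1 the log2 fold change of the Cnot4 uaRNA was 1.55. Some named rises have an annotated opposite-strand gene within 10 kb upstream, whose reads could enter the uaRNA. These are Magt1 (Cox7b), Cnot8 (Gm12247) and, within 1 kb, Phpt1 (Gm26702), Ampd2 (Gm12500), Cdkl3 (Gm26551) and Taf7 (Gm42416 among others). Bmp4, Avpi1, Cnot4 and Vps4b have none there, but the annotated opposite-strand genes Gm15217 and Gm15222 overlap Bmp4 itself. The uaRNA of Eral1, a gene for mitochondrial ribosome assembly (chromosome 11, 78073376 to 78080370, minus strand), fell from 98.6 ± 10.7 to 47.1 ± 13.3 (SD, n = 3; log2 fold change -1.08, adjusted p = 0.0232). The uaRNAs of Prkcz (log2 fold change -1.06), Tmem94 (-1.01), Rnf17 (-0.99), Dus1l (-0.98), Abraxas2 (-0.83), Mrpl45 (-0.80) and Dennd2a (-0.78) also fell. These 8 were the only falls that met the naming rule, and all 8 lost their call without siZC3H4 replicate 3 (adjusted p up to 0.144) and without a minimum value (up to 0.13). Leaving out siNT replicate 1, 2 or 3 lost 2, 6 and 5 of these calls, and leaving out siZC3H4 replicate 1 or 2 lost 7 each. Prkcz, Rnf17, Dus1l, Abraxas2, Mrpl45 and Dennd2a lost theirs with DESeq2, Abraxas2 and Dennd2a with a pseudocount of 0.5, and Dus1l under both rescalings.

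Over all tested uaRNAs the median log2 fold change was 0.59 (1.501-fold), and 84.19% of them lay above 0. The median uaRNA value of a library was 11.8, 12.89 and 10.79 in siNT replicates 1, 2 and 3 and 21, 18.05 and 17.75 in siZC3H4 replicates 1, 2 and 3 (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). At an unadjusted p under 0.05, 1338 uaRNAs were higher and 45 lower. In 1449 uaRNAs all siZC3H4 libraries lay above all siNT libraries and in 74 below, together 46.4%, where chance gives 10%. The share that rose was 24.3% at mean values from 5 to 10, 32.7% from 20 to 50 and 17.1% at 100 or more, where the median log2 fold change was 0.18. In tests chosen after the data were seen, of the 12 gene lists with at least 5 tested uaRNAs, camera found 0 whose uaRNAs moved apart from the other uaRNAs, and 1 at an unadjusted p under 0.05, the ribosomal proteins (12 of 27 rose; adjusted p = 0.318, and 0.909 with an estimated correlation). fry, also chosen then, tests movement in 1 direction without comparing with other uaRNAs, and called all 12 lists higher. The number of rises was 593 without siNT replicate 3, and 348, 564 and 472 without siZC3H4 replicates 1, 2 and 3. The number of falls was 7 and 9 without siNT replicates 2 and 3, and 7, 7 and 3 without siZC3H4 replicates 1, 2 and 3. Rescaled to the uaRNAs themselves, which sets their typical change near 0 by construction, 59 uaRNAs were higher and 34 lower, and the median log2 fold change was -0.02.

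The genes downstream of rising uaRNAs seldom rose with them. Bmp4 mRNA was at 438 ± 58.6 in siNT and 442 ± 102 in siZC3H4 (SD, n = 3), Magt1 mRNA at 747 ± 166 and 703 ± 48.2, and Cnot8 mRNA at 1535 ± 335 and 1767 ± 243. Of the own genes of the 18 named uaRNAs, 0 passed the threshold in limma, edgeR or DESeq2, and 0 had an unadjusted p under 0.05 in limma, and their log2 fold changes ran from -0.29 (Prkcz) to 0.29 (Cdkl3). In 3266 pairs of a uaRNA and its gene, the uaRNA's log2 fold change exceeded the gene's by a median of 0.50, and the difference was above 0 in 77.5% of pairs. The test of the difference called 497 pairs with the uaRNA above its gene and 17 below. With no minimum value it called 51 above and 3 below in 5797 pairs, and at a mean of at least 50 it called 104 and 12 in 499 pairs. Across genes, which are not independent replicates, the log2 fold changes of uaRNA and gene had a Pearson r of 0.0358 and a Spearman rho of 0.0273. Among own genes of the 903 rising uaRNAs in these pairs, 28 rose (3.1%) and 1 fell, where the share of all paired genes would give 22.7 rises. The number of called pairs moved with single libraries. Without siNT replicates 1, 2 and 3, 817, 213 and 189 uaRNAs were above their gene and 27, 5 and 9 below. Without siZC3H4 replicates 1, 2 and 3, 15, 50 and 18 were above and 2, 3 and 2 below, while the median difference stayed between 0.40 and 0.62 in all 6 fits.

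**Figure D2:**
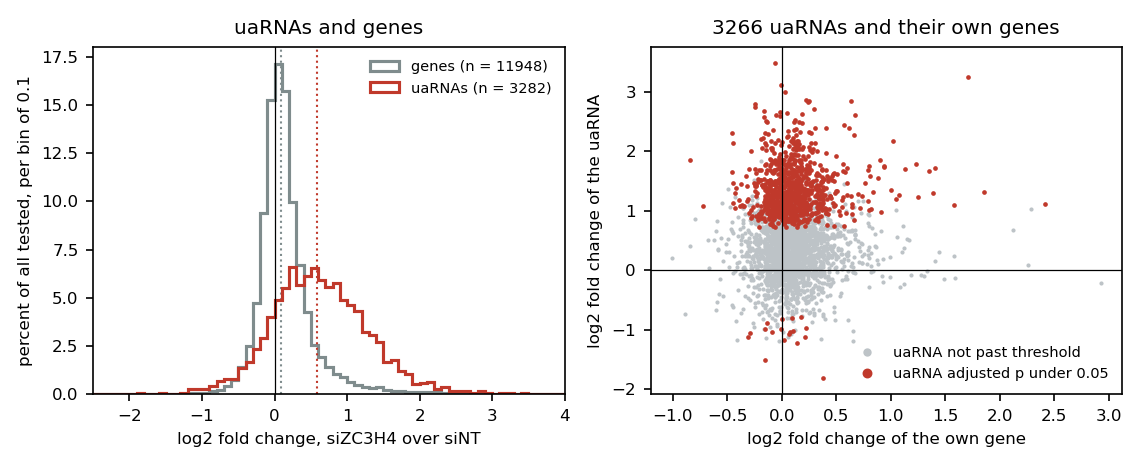
The histogram gives the share of tested uaRNAs (n = 3282) and genes (n = 11948) by log2 fold change of siZC3H4 over siNT, on the log2(value + 1) scale, with dotted lines at the medians (0.59 and 0.09). The scatter sets each uaRNA's log2 fold change against that of its own gene for 3266 pairs, with uaRNAs past the threshold in red; the Pearson r across genes is 0.0358.

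The exon-based table addresses which mature transcripts differ between the labels. Dglucy, which encodes D-glutamate cyclase (ENSMUSG00000021185, chromosome 12, 100779095 to 100872354, plus strand), rose from 122 ± 7.69 to 1289 ± 279 (SD, n = 3), a log2 fold change of 3.37 ± 0.18 (SE) at an adjusted p of 0.000597. Nkx2-9, a homeobox gene (chromosome 12, 56611393 to 56613178, minus strand), rose from 16.1 ± 2.25 to 94.3 ± 19.8 (SD, n = 3; log2 fold change 2.46). Gnmt, which encodes glycine N-methyltransferase (chromosome 17, 46725664 to 46729165, minus strand), fell from 123 ± 17.4 to 34.5 ± 5.45 (SD, n = 3; log2 fold change -1.81, adjusted p = 0.00173). Of 11948 tested genes, 622 rose (5.206%), by a median of 2.055-fold, and 64 fell (0.536%), by a median of 1.699-fold.

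Among genes with a symbol that is not only an identifier, the largest rise was that of Stkld1, whose start lies 399 bases from that of Surf4 on the opposite strand (5.77 ± 2.37 to 66.0 ± 4.25, SD, n = 3; log2 fold change 3.38). Iqch, whose start lies 214 bases from that of Aagab on the opposite strand, rose from 3.78 ± 1.33 to 38.0 ± 6.11 (SD, n = 3). Further rises were those of Ropn1l (log2 fold change 2.94), Prss48 (2.92), the BMP receptor gene Bmpr1b (2.55), Rnf43, which encodes a ubiquitin ligase that removes Wnt receptors (2.52), and Ly6g6c (2.47). By p, AU040972 (1.00 ± 0.41 to 22.6 ± 2.24, SD, n = 3; log2 fold change 3.58, and 2.20 with a pseudocount of 5) and 4930432K21Rik (124 ± 13.6 to 611 ± 32.3, SD, n = 3; 276 bases from the start of Cc2d1a) stood beside Dglucy. The other named falls were those of the nucleosome-binding protein gene Hmgn3 (log2 fold change -1.48), Hapln4 (-1.45), the meiotic entry gene Stra8 (-1.38), Zfr2 (-1.33), Adam11 (-1.19), Nat8l (-1.19), Card9 (-1.11), Pip5kl1 (-1.02) and Padi2, a peptidylarginine deiminase gene (-1.02). The 9 rises described here, of the 10 that met the naming rule, held whichever library was left out. Among the falls, Hmgn3, Stra8, Zfr2 and Pip5kl1 lost their call in some of these fits: 2 and 3 genes without siNT replicates 2 and 3, and 2, 2 and 3 without siZC3H4 replicates 1, 2 and 3 (adjusted p up to 0.0828).

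**Figure D3:**
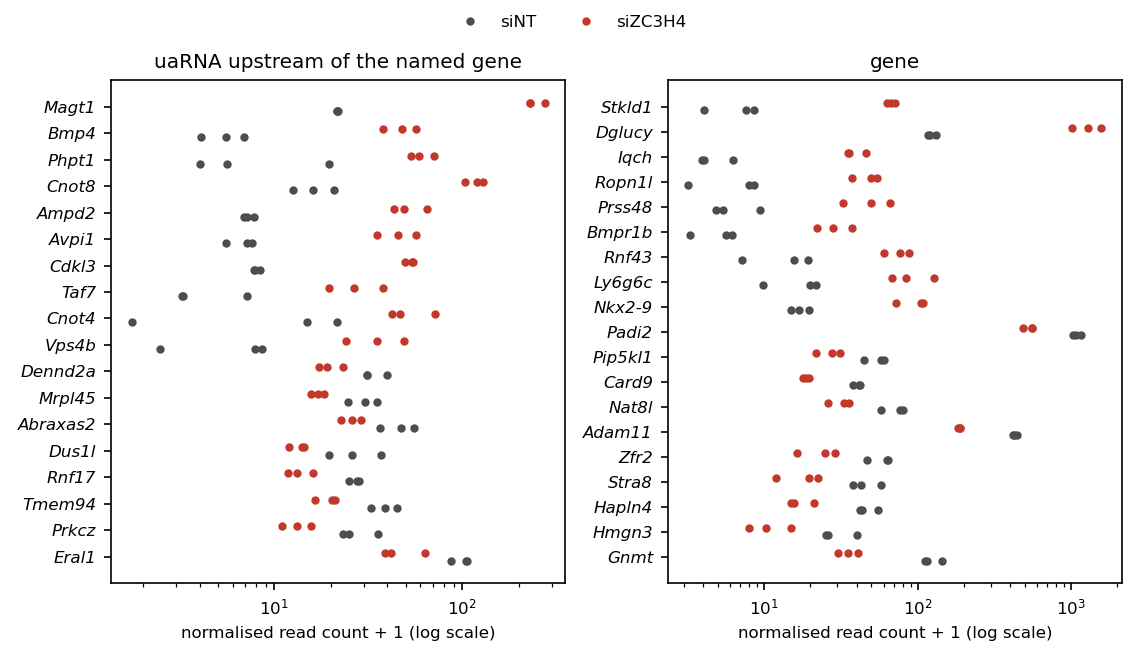
Each point is 1 library's normalised read count plus 1 on a log axis, for the uaRNAs (named by their gene) and the genes described for the largest rises (9 genes) and falls (10 genes); grey is siNT and red is siZC3H4 (n = 3 each). The naming rule admits only those in which the 3 libraries of a label lie apart from the 3 of the other, so that separation follows from the choice.

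Rises were more frequent among weakly expressed genes and long noncoding RNAs. The median siNT value of genes that rose was 60.6, against 736.5 for genes not past the threshold. Of long noncoding RNAs, 95 of 485 rose (19.6%), and of protein-coding genes 521 of 11382 (4.58%). With expression level held fixed, the odds ratio for long noncoding RNAs was 1.69 (95% confidence interval 1.3 to 2.19). The share of genes that rose went from 16.9% at mean values from 10 to 30 to 0.404% at 3000 or more. At those levels 8 of 818 and 2 of 1734 genes fell, so falls too were more frequent among weakly expressed genes. The median log2 fold change of all genes was 0.09, and after rescaling by the median ratio of the exon-based table it was -0.02, with 566 genes higher and 131 lower. At an unadjusted p under 0.05, 1743 genes were higher and 387 lower. All siZC3H4 libraries lay above all siNT libraries in 2336 genes and below in 694, together 25.36%, where chance gives 10%. Without siNT replicate 1, 835 genes were higher and 228 lower, and without siNT replicates 2 and 3, 407 and 440 were higher and 31 and 23 lower. Without siZC3H4 replicates 1, 2 and 3, 256, 304 and 289 were higher and 28, 15 and 19 lower. edgeR with TMM factors of the exon-based table, chosen after the data were seen, called 473 higher and 156 lower.

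**Figure D4:**
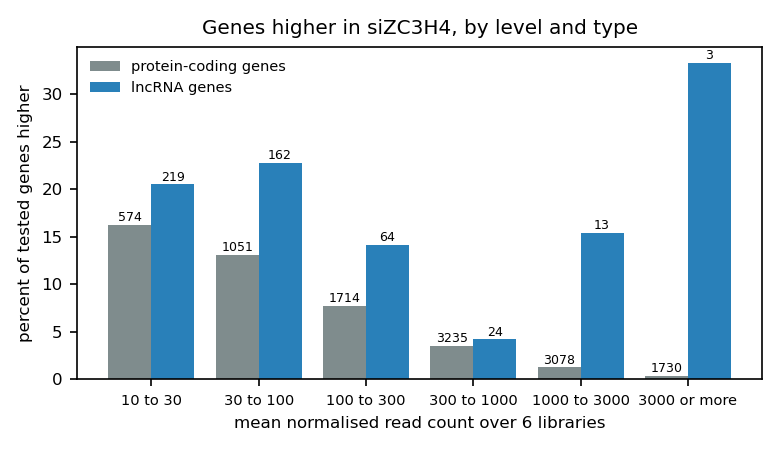
Bars give the percent of tested genes past the threshold and higher in siZC3H4, by the mean normalised read count over 6 libraries, for protein-coding genes (grey) and long noncoding RNA genes (blue); the number over a bar is the number of genes tested. Among protein-coding genes the share falls from 16.2% to 0.347% over the range, and the bins of long noncoding RNAs from 1000 upwards hold only 13 and 3 genes.

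Targets of p53 were the 1 list of 23 that camera called (adjusted p = 0.000532), with an adjusted p = 0.841 with an estimated correlation, at which 0 of the 23 lists were called or had an unadjusted p under 0.05. fry, which tests a list against no change and not against the other genes, gave an adjusted p of 0.0389. Of 21 tested targets, 4 rose and 0 fell, 8 rose when adjusted over the list alone, and 20 had a log2 fold change above 0 (median 0.40). Pmaip1, which encodes the apoptosis protein NOXA, rose from 214 ± 29.5 to 370 ± 41.1 (SD, n = 3; adjusted p = 0.0265). Perp, a gene for a desmosomal membrane protein, rose from 73.2 ± 20.7 to 148 ± 20.1 (SD, n = 3; adjusted p = 0.0335). Phlda3, which encodes a repressor of AKT signalling (1955 ± 367 to 3411 ± 430), and the kinase gene Plk2 (553 ± 116 to 1061 ± 237) also rose (SD, n = 3). The list's call held without each library in turn (adjusted p from 0.000213 to 0.0342), whereas all 4 genes lost theirs under both rescalings to the exon-based table (adjusted p from 0.0756 to 0.121). All 4 genes kept their call without siNT replicate 1, whose gene values were low, and lost it without any other library. Perp, Phlda3 and Plk2 also lost it without a minimum value, and Plk2 with a pseudocount of 0.5.

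Genes of naive pluripotency did not pass the threshold: 0 of 24 in limma, edgeR and DESeq2, also when adjusted over the list alone (camera adjusted p = 0.35), with 2 higher and 1 lower at an unadjusted p under 0.05. camera compares a list with the other genes, whose median lay above 0. Its direction was down for naive pluripotency, germline, fibroblast, Restrictor, exosome, stress, immediate early and cholesterol genes, although the median of each of these lists lay above 0 (0.01 for naive pluripotency). Klf4, a core pluripotency factor, was at 9397 ± 1894 in siNT and 6779 ± 389 in siZC3H4 (SD, n = 3; log2 fold change -0.45, adjusted p = 0.221), and passed under both rescalings and without siNT replicate 1. Dppa2 was at 213 ± 66.3 and 326 ± 35.9 (SD, n = 3; adjusted p = 0.211). Of 14 formative and primed pluripotency genes 2 rose, 3 when adjusted over the list alone. These were Lefty1, which encodes a Nodal antagonist (2082 ± 448 to 5571 ± 1332), and the ETS factor gene Etv4 (269 ± 23.0 to 607 ± 144; SD, n = 3). Otx2 was at 137 ± 19.6 and 221 ± 46.9 (adjusted p = 0.108). The camera adjusted p of this list was 0.0794, and it was 0.0332 after rescaling and 0.841 with an estimated correlation. It was 0.032, 0.216 and 0.0698 without siNT replicates 1, 2 and 3, and 0.0153, 0.0283 and 0.249 without siZC3H4 replicates 1, 2 and 3.

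Markers of other lineages gave 0 or 1 call in each list. Of 11 primitive endoderm genes 1 rose, the transcription factor gene Gata4 (49.8 ± 2.46 to 79.6 ± 7.29, SD, n = 3; adjusted p = 0.0241), with a camera adjusted p of 0.276 for the list and 1 rise when adjusted over the list alone. At an unadjusted p under 0.05, 6 of the 11 were higher and 0 lower. The Gata4 call was lost with edgeR, DESeq2, limma with trend, both rescalings and without any library other than siNT replicate 1, and Lrp2 of the same list had an adjusted p of 0.114. Of 7 mesoderm and primitive streak genes 0 passed in limma, edgeR and DESeq2 or when adjusted over the list alone, and 3 had an unadjusted p under 0.05, while all 7 lay between log2 fold changes of 0.43 and 0.98 (Mesp2 0.49, Cdx1 0.76). That list's camera adjusted p was 0.0794, 0.0332 after rescaling and 0.841 with an estimated correlation. It was 0.0771, 0.167 and 0.0621 without siNT replicates 1, 2 and 3, and 0.0064, 0.0781 and 0.249 without siZC3H4 replicates 1, 2 and 3. Of 8 neural genes 1 rose, the transcription factor gene Neurod1 (47.5 ± 8.01 to 128 ± 21.5, SD, n = 3), and camera gave an adjusted p of 0.665 for the list and fry 0.029. Adjusted over the list alone, 2 neural genes were higher and 1 lower. Map2 had an adjusted p of 0.0575 and passed with edgeR, DESeq2, both rescalings and without siNT replicate 1. Of 16 germline genes 1 rose, the histone reader gene Zcwpw1 (283 ± 39.8 to 511 ± 68.1), and Dazl, which encodes an RNA-binding protein of germ cells, was at 444 ± 61.7 and 284 ± 29.9 (SD, n = 3; adjusted p = 0.053). Dazl passed with edgeR, DESeq2 and without siNT replicate 1, the germline camera adjusted p was 0.809, and adjusted over the list alone 1 germline gene was higher and 1 lower. Of 5 fibroblast (feeder) markers 0 passed (camera adjusted p = 0.594; Col5a1 599 ± 105 and 623 ± 71.1, SD, n = 3), and of 4 tested trophoblast markers 0 passed (Krt18 log2 fold change 0.33), with 0 in edgeR and DESeq2, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05 for both lists. The lists of the 2-cell-like state, replication-dependent histones and mitochondrially encoded genes had 0 tested members. Zcwpw1 lost its call without siNT replicate 3 and without each siZC3H4 replicate, and Neurod1, Lefty1 and Etv4 kept theirs without any 1 library.

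Among the complexes of nuclear RNA control, Integrator had 3 of 16 genes rise and 0 fall (3 and 0 adjusted over the list alone; camera adjusted p = 0.725). Nabp1, which encodes a single-stranded DNA-binding protein that partners INTS3, rose from 268 ± 26.7 to 688 ± 112 (SD, n = 3; adjusted p = 0.00434). Ints6 rose from 1138 ± 65.7 to 2084 ± 228 and Ints3 from 3792 ± 730 to 6927 ± 360, while Ints10 was at 2333 ± 286 and 1810 ± 146 (SD, n = 3; adjusted p = 0.235). Ints10 passed without siNT replicate 1. Ints6 lost its call without siZC3H4 replicates 2 and 3, and Ints3 without siNT replicate 2 and each siZC3H4 replicate. In limma 0 of 20 genes passed for the nuclear exosome and its cofactors (camera adjusted p = 0.281; Exosc3 log2 fold change -0.23), 0 of 22 for cleavage and polyadenylation (0.809; Cstf2t 0.27) and 0 of 23 for elongation control (0.809; Ccnt2 0.31). These 3 lists also had 0 calls in edgeR and DESeq2, 0 when adjusted over the list alone and 0 genes at an unadjusted p under 0.05. Of 15 long noncoding RNAs of the fixed list 3 rose and 1 fell, 4 and 1 when adjusted over the list alone (camera adjusted p = 0.276). Meg3, a nuclear RNA of the imprinted Dlk1 region, fell from 3911 ± 71.2 to 2201 ± 124 (SD, n = 3; adjusted p = 0.00748), and lost its call without siZC3H4 replicate 2. Platr26 rose from 42.4 ± 14.5 to 142 ± 23.6 (SD, n = 3), Lncpint had a log2 fold change of 1.19 and Platr27 of 0.70. Lncpint lost its call with edgeR, DESeq2 and limma with trend and without siNT replicate 2 or siZC3H4 replicate 1 or 3, and Platr27 without a minimum value and without any library other than siNT replicate 1. Of 15 small nucleolar RNA host genes 1 rose, 3 when adjusted over the list alone (camera adjusted p = 0.269, fry 0.0114): Snhg12 went from 1355 ± 170 to 2580 ± 264 (SD, n = 3), a call lost without siZC3H4 replicate 1 or 3. Without siNT replicate 1 the camera adjusted p of these host genes was 0.0225, and without each other library it ran from 0.188 to 0.434.

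The MEK-ERK, Wnt and immediate early lists had 1 rise each, also when adjusted over each list alone. Among 14 MEK-ERK feedback targets, genes induced by the kinase pathway that the 2i medium inhibits, Etv4 rose, while Dusp4 (log2 fold change 0.52) and Dusp6 (0.51) passed only without siNT replicate 1 (camera adjusted p = 0.343). Among 12 Wnt targets Rnf43 rose from 13.0 ± 6.20 to 74.2 ± 13.9 (SD, n = 3; camera adjusted p = 0.276). Among 20 immediate early genes Ccn2, which encodes a matricellular growth factor, rose from 95.5 ± 23.9 to 199 ± 49.6 (SD, n = 3; camera adjusted p = 0.567), a call lost without a minimum value and without any library other than siNT replicate 3. Of 6 interferon response genes 0 passed in limma or edgeR, 1 when adjusted over the list alone: Irf9 was at 436 ± 71.5 and 656 ± 17.5 (SD, n = 3; adjusted p = 0.0601, camera adjusted p = 0.293), and passed with DESeq2 and without siNT replicate 3. Of 22 genes of the integrated stress and unfolded protein response 0 passed in limma or edgeR or when adjusted over the list alone (camera adjusted p = 0.269), with a median log2 fold change of 0.02 and a mean of -0.01. Sesn2 (log2 fold change 0.48) and Cth (-0.45) were the 2 with an unadjusted p under 0.05, and both passed with DESeq2.

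Housekeeping lists gave 0 calls in limma: 0 of 22 for cholesterol and lipid synthesis (camera adjusted p = 0.349; Insig1 log2 fold change -0.25), 0 of 19 for glycolysis (0.276; Slc2a3 -0.36) and 0 of 44 for ribosomal proteins (0.293; Rps9 0.31). In camera the glycolysis list passed without siNT replicate 2 (adjusted p = 0.0407, and 0.181 to 0.587 without each other library). The ribosomal protein list passed without siNT replicate 1 (0.0225, and 0.249 to 0.89 without each other library), and fry gave the ribosomal proteins 0.0321. Adjusted over each list alone, and in edgeR and DESeq2, the 3 lists again had 0 calls, and Rps9 was the 1 gene among them with an unadjusted p under 0.05.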

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

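The edgeR fits with TMM factors of the exon-based table, the fit on uaRNAs with no annotated opposite-strand gene within 10 kb upstream, the rescaled and leave-one-out list tests, and fry with the replicate block were chosen after the data were seen. uaRNAs higher in the libraries labelled siZC3H4 outnumbered lower ones in every setting run, at 906 against 18 as reported. The counts were 488 and 9 without a minimum value, 181 and 4 at a mean of at least 50, which tests fewer uaRNAs, 580 and 6 with DESeq2, and 592 and 11 for uaRNAs with no annotated opposite-strand gene, which is a part of those tested. Rescaled to the uaRNAs themselves they were 59 and 34, and the median log2 fold change of -0.0242 follows from that scale. With the replicate block 9 uaRNAs were lower, and leaving out 1 library, which leaves fewer samples, gave 348 to 786 higher and 3 to 13 lower. The median uaRNA log2 fold change of 0.59 was 0.449 with a pseudocount of 5 and 0.313 at a mean of at least 50, where its difference from the own gene was 0.257 instead of 0.50. Genes higher (622) were 341 with the replicate block and 256 to 835 with 1 library left out. Genes lower (64) were 131 and 98 under rescaling by the median ratio and the upper quartile of the exon-based table, 116 with DESeq2, 156 with edgeR and TMM factors, 21 with the block, and 15 to 228 with 1 library left out. The median gene log2 fold change of 0.09 was -0.0155 under the median ratio and ran from -0.0086 (without siNT replicate 1) to 0.141. That of Zc3h4 ran from -0.236 to 0.151 with 1 library left out. Of 23 gene lists, camera called 1 as reported, 0 with an estimated correlation, 3 with the block (p53 targets 0.000497, formative and primed pluripotency 0.0129, mesoderm and primitive streak 0.00257), 3 after rescaling and 1 to 4 with 1 library left out. fry called 4 lists, and 0 with the block (p53 targets 0.104, neural markers 0.104, small nucleolar RNA host genes 0.0523, ribosomal proteins 0.0893). Replicate numbers were not treated as pairs in the main fits. The correlation of residuals between libraries of the same number ran from 0.0106 to 0.132 in uaRNAs and from 0.0612 to 0.214 in genes. Between libraries of different numbers it ran from -0.19 to 0.128 in uaRNAs and from -0.301 to 0.171 in genes. Every same-number correlation was above 0, so replicate sets are not excluded. If they exist, the counts with the replicate block apply.

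Of 99 named results besides Zc3h4, 57 were called. Of these, 31 kept their call in every setting, 26 lost it in at least 1 and 0 changed direction, while 12 uncalled results passed in at least 1 setting. With the replicate block 17 of the 57 were not called: the uaRNAs of Cnot4, Abraxas2, Dennd2a, Dus1l and Mrpl45, and the genes Ccn2, Gata4, Hmgn3, Ints3, Lncpint, Phlda3, Pip5kl1, Platr27, Plk2, Pmaip1, Snhg12 and Zcwpw1 (adjusted p from 0.0519 to 0.104). Direction changed for 11 uncalled genes with log2 fold changes near 0. Under the median ratio and the upper quartile of the exon-based table, values were -0.059 and -0.0345 for Vps4b, -0.0342 and -0.00977 for Eral1, -0.0972 and -0.0728 for Abraxas2, -0.0755 and -0.0511 for Phpt1, and -0.0375 and -0.0131 for Col5a1. Under the median ratio alone, Mrpl45 had -0.012 and Tmem94 -0.00462. Bmp4 had 0.0144 with edgeR and 0.0143 with DESeq2. With 1 library left out, log2 fold changes ran from -0.175 to 0.217 for Vps4b, -0.0162 to 0.184 for Tmem94, -0.171 to 0.164 for Bmp4, -0.0341 to 0.0515 for Dus1l and -0.151 to 0.182 for Abraxas2. They ran from -0.191 to 0.106 for Magt1, -0.133 to 0.133 for Phpt1, -0.23 to 0.143 for Cnot4 and -0.0729 to 0.183 for Col5a1. Beyond what fewer samples, fewer uaRNAs tested or the scale itself account for, the cause was not tested. Rescaling by ERCC sequences was not run. With reads as few as those of most uaRNAs, limma called 17.6% of simulated 2-fold changes. The simulation changed 200 entries in both directions, whereas 906 of 3282 uaRNAs rose in the data, so the share called in the data may differ. uaRNAs that did not pass are not shown to be unchanged.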

Other observations

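The tests of uaRNAs by gene list (Fisher's exact test, camera and fry) and by the level of the gene were chosen only after the result was seen. So were the test for swapped libraries and the test on genes without an annotated opposite-strand neighbour. The rescaled and leave-one-out fits behind the tests of library scale were planned. The limits that decide those tests of scale were written after the result was seen. uaRNAs of naive pluripotency genes rose more often than other uaRNAs: 11 of 16 (68.8%) against 895 of 3266 (27.4%; Fisher's exact p = 0.000705, 0.00846 adjusted over 12 lists). That test takes genes as independent. It did not hold fixed the level of the gene or of the uaRNA, with which the share of rises varied. camera gave the same uaRNA list an adjusted p of 0.623, and an adjusted p of 0.909 with an estimated correlation. The uaRNA of Nanog, a core pluripotency factor, rose from 13.4 ± 6.82 to 53.3 ± 14.3, that of Zfp42 from 15.4 ± 5.07 to 57.2 ± 13.4, and that of Pou5f1 from 54.3 ± 24.7 to 128 ± 15.6 (SD, n = 3). The uaRNAs of Sox2 (log2 fold change 1.65), Sall4, Tdgf1, Dppa5a, Tcl1, Tfcp2l1, Fgf4 and Tbx3 also rose, whereas those of Klf4, Klf2, Gbx2, Nr5a2 and Dppa2 did not pass (log2 fold change -1.20 for Dppa2, adjusted p = 0.0583). The genes themselves did not pass the threshold, with log2 fold changes of -0.07 for Nanog, 0.07 for Sox2 and 0.05 for Pou5f1. Rescaled to the exon-based table, 8 of the 16 uaRNAs rose (adjusted Fisher's exact p = 0.0756), and rescaled to the uaRNAs themselves, 2 of 16 (0.354).

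uaRNAs of strongly expressed genes rose more often than those of weakly expressed genes. Ordered by the level of the gene in groups of 654 or 653 uaRNAs, 21.3%, 25.9%, 27.3%, 28.9% and 34.9% rose from the lowest group to the highest. With the uaRNA's own level held fixed, the odds ratio of the highest against the lowest group was 1.91 (95% confidence interval 1.48 to 2.47). That interval takes uaRNAs as independent and does not measure the spread between libraries.

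The rise of uaRNAs in the libraries labelled siZC3H4 gave 924 calls, and 1 of the 10 splits of the 6 libraries, the real one, gave as many, the highest other giving 0; with 10 splits the share cannot fall under 0.05. The tables argue against the scale of the libraries as the whole cause, since the lowest median log2 fold change over both rescalings to the exon-based table and the fit without siNT replicate 1 was 0.489. Reads of annotated genes on the uaRNA strand are argued against as the whole cause by a median of 0.641 for 2048 uaRNAs with no annotated opposite-strand gene within 10 kb upstream. The bootstrap 95% interval of 0.601 to 0.68 resamples uaRNAs with the 6 libraries held fixed, so it does not measure the spread between libraries. The 1234 uaRNAs with such a gene, among them those of Magt1, Cnot8, Phpt1, Ampd2, Cdkl3 and Taf7, had a median of 0.498. For these, such reads were not examined. Opposite-strand genes that overlap only the gene itself, as for Bmp4, were not left out of the 2048. The nuclear noncoding RNAs Meg3, Firre, Neat1 and Malat1 (4 measured of 7 listed) had a median of 0.0243 (SD 0.475), below the uaRNA median of 0.59 by more than their spread. As a set they gave no sign of a larger share of nuclear RNA. They cannot exclude one, since the SE was 0.26 for Firre, 0.32 for Neat1 and 0.27 for Malat1, and Meg3 was itself called lower. An effect of the siRNA on ZC3H4, whose protein was not analysed here, stays open and may be held only as a hypothesis, since the target mRNA was not lower.

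More genes rose than fell, with 686 calls in the real split and 0 in the highest other, so that 1 of 10 splits gave as many, a share that cannot fall under 0.05. Scale alone is argued against by a ratio of rises to falls of 4.32 after rescaling by the median ratio of the exon-based table, against 9.72 as deposited and 3.66 without siNT replicate 1. Read-through from a measured same-strand gene ending within 10 kb upstream is argued against as a broad cause. Such a gene was found for 102 of 622 rising genes (16.4%) and 1934 of 11262 uncalled genes (17.2%). The odds ratio was 1.07 (95% confidence interval 0.856 to 1.34). Single genes are not decided by this, and Ropn1l, Rnf43 and Ly6g6c have such a neighbour. Read-through from overlapping, unmeasured or more distant genes was not tested. Transcription from a neighbouring promoter running into the gene may account for part of the rises. An opposite-strand start of another measured gene within 10 kb upstream was found for 199 of 622 rising genes (32%) and 2818 of 11262 uncalled genes (25%). The odds ratio was 1.51 (95% confidence interval 1.25 to 1.82), whose lower bound lies under the 1.5 set before that test was run. Reads across promoters were not examined for any gene, including Stkld1 and Iqch. The 4612 genes with no annotated opposite-strand gene within 10 kb upstream or overlapping them lack such a neighbour by selection. Among them 214 rose (4.64%) and 27 fell (ratio 7.93), while 5.56% of the other genes rose, so an annotated neighbour is not the whole cause. Unannotated transcription was not tested for these genes, and an effect of the siRNA stays open. For the remaining rises both a neighbouring promoter and the siRNA stay open.

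Zc3h4 mRNA was not lower in the libraries labelled siZC3H4. Library scale alone did not hide a separation of the groups. After rescaling by the median ratio of the exon-based table, 0 of the 3 siZC3H4 libraries (2149, 2117 and 2545) lay below every siNT library (2040, 2522 and 2867). That count rests on siNT replicate 1 (2040), which stood apart, since 2149 and 2117 lie below the other siNT libraries. At the deposited scale the log2 fold change without that library was -0.24, so a modest fall is not excluded. In 3 of 3 libraries labelled siZC3H4 the median uaRNA value lay above that of every siNT library. A swap of 2 libraries between the groups is argued against only if uaRNA levels follow the siRNA, which is itself a hypothesis here. An exchange of the whole groups cannot be told by this test. No biological explanation, such as timing or a change at the protein level, was tested, and these stay open.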
